A study of Mus musculus with 9 samples.

How the data were processed

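RNA sequencing of total RNA from mouse small intestine was analysed from the deposited processed table, with 9 libraries in 3 groups of 3 (WT, Ripk3-KO and VilCre-Ripk3fl/fl) assigned from the sample titles. The labels name TRIzol and RNAlater, ribosomal RNA removal and stranded library kits. The authors list Trimmomatic, STAR, HTSeq and DESeq2 and the genome build mm10, with roles and versions not given in the sources used here. The deposited table gives whole-number read or fragment counts per gene, and whether strand was used in counting is not stated, so genes that overlap on opposite strands are uncertain. The deposited table also gives CPM per library, which the authors divided by a scaled library size, since the columns sum to between 923764 and 1019912. The authors' deposited log2 fold changes, p-values and FDR-adjusted p-values against WT cover 26529 genes and were read only for a comparison, and 1066 of those genes have 0 counts in all libraries. The 18 RPKM and TPM columns were not used, since the counts were. Of 48708 genes in the table, 1 line was not analysed here and 23245 had 0 counts in every library. Of the gene identifiers, 48348 were found in GENCODE release M21, 48328 at an overlapping position and 46198 with the same symbol.

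Total counts ranged from 25375499 to 41038990 per library. Counts were tested with edgeR 4.0.16 in R 4.3.3, using filterByExpr by group (16539 genes kept), TMM scaling (factors 0.932 to 1.043), and a robust quasi-likelihood fit of all 9 libraries with 1 mean per group, which left 6 residual degrees of freedom. The common biological coefficient of variation was 0.081. Tests were 2-sided, with Benjamini-Hochberg adjusted p-values and a threshold of 0.05. A gene past the threshold is said to have been called, and to have risen or fallen. Group values are mean CPM with the SD over 3 libraries. Fitted log2 fold changes used a prior count of 0.125, and their SE was taken from the quasi-likelihood F statistic. Where every library of a group had 0 counts, the fold was computed against a floor of 3 counts per library and is a lower bound. Where a group had only a few counts, the ratio of counts summed over the group and scaled to library size is given with its exact binomial 95% interval, which covers counting error only.

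Lists of genes were written before the data were examined. Each was tested against all other genes with camera (limma 3.58.1) with a preset correlation between genes of 0.01, adjusted over 42 lists in each comparison, and again with an estimated correlation and with fry. Some genes belong to more than 1 list, such as the defensins shared by the Paneth cell and alpha-defensin lists, and Clps of the Paneth cell list and Reg1, Reg2 and Klk1 of other lists are also made by pancreas. Several enteroendocrine markers, such as Chga, Sst and Gcg, are also made by pancreatic islets. Named genes followed a rule also fixed before the data were examined. It covers 12 genes of necroptosis and interferon signalling, the 8 higher and 8 lower genes with the largest fitted log2 fold change in each comparison (mean CPM of at least 1, groups not overlapping, no segments, sex-linked genes or symbols of predicted models such as Gm or Rik names), up to 2 higher and 2 lower members of each list with the smallest p, and genes of results set apart in the closing section. The 12 genes were fixed for the comparisons with WT and are also given for the comparison of the 2 deletions. Some genes that the rule names are not used here. Gene Ontology terms with 15 to 300 tested genes were tested with camera in the same way, a choice made after the data were seen.

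Similarity was described with principal components and Spearman correlations of log2 CPM. Replicate numbers were checked as pairs: residuals of libraries with the same number in different groups correlated between -0.04 and 0.09, and 2 of 9 libraries matched best with their own number, so the numbers were not used as pairs. Shared changes were set beside 20 simulated draws of unchanged groups against the same WT libraries. The procedure was tested on simulated data with 50 genes altered at each size. At 1.25-fold, 1.5-fold, 2-fold and 4-fold it recovered 48, 62, 78 and 84% in Ripk3-KO against WT, 50, 64, 72 and 86% in VilCre-Ripk3fl/fl against WT, and 46, 68, 74 and 82% between the deletions. False calls made up 2.16, 8.72 and 3.57% of all calls, and 2, 0 and 1 of 42 lists were called.

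The alternatives were RLE size factors, upper-quartile scaling, no filter beyond 1 read, a filter at 1 CPM in 3 libraries, fits of only the 2 groups compared, DESeq2 1.42.0, limma-voom without and with library quality weights, the replicate number as a block, and leaving out each library in turn. Lists were tested under DESeq2 with cameraPR on its Wald statistics. After the data were seen, 3 alternatives were added: TMM factors without pancreas, adipocyte and erythroid list genes, leaving out genes on the X and Y chromosomes, and leaving out pancreas-like, adipocyte and erythroid genes.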

Results

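RNA from the small intestine of C57BL/6 mice with acute graft-versus-host disease, in which transplanted immune cells attack the host, was sequenced in 9 libraries. There were 3 groups of 3 libraries: wild type (WT), Ripk3-KO (Ripk3 deleted in the whole body) and VilCre-Ripk3fl/fl (Ripk3 deleted through Villin-cre, which acts in the intestinal epithelium). Ripk3 encodes a kinase of necroptosis, a form of regulated cell death. The labels gave an age of postnatal week 8 for each. The genotype labels do not say whether they also hold for the transplanted cells, which may supply reads of immune cell genes. Total counts were 32225648, 29487575 and 27810868 in WT replicates 1 to 3, 36618034, 36869253 and 41038990 in Ripk3-KO, and 25375499, 27903666 and 29410940 in VilCre-Ripk3fl/fl. A floor of 3 counts corresponded to between 0.071 and 0.127 CPM (counts scaled to library size) per library, for counting error only. The p-values measure only the spread between these libraries, which may be technical, since the labels do not say that each library came from a separate animal and the design text calls the samples duplicated.

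The libraries grouped by genotype. Across genes, Spearman correlations of log2 CPM were 0.995 within WT, 0.994 to 0.995 within Ripk3-KO and 0.991 to 0.992 within VilCre-Ripk3fl/fl, against 0.955 to 0.973 between groups. Principal component 1 held 45.8% of the variance and placed WT between -71.5 and -71.2, VilCre-Ripk3fl/fl between 20.5 and 25.7 and Ripk3-KO between 47.8 and 49.8. Component 2 held 30.2% and ran from -62.3 in a VilCre-Ripk3fl/fl library to 46.5 in a Ripk3-KO library. Several markers outside the question of the study also moved with the groups. Xist, the transcript of the inactive X chromosome, was at 276 ± 5.75 CPM (SD, n = 3) in Ripk3-KO, 8.46 ± 1.99 in WT and 7.50 ± 0.415 in VilCre-Ripk3fl/fl. The Y-linked gene Ddx3y was at 0.476 ± 0.213 CPM in Ripk3-KO, 39.8 ± 1.72 in WT and 38.1 ± 4.58 in VilCre-Ripk3fl/fl. High Xist with little Ddx3y marks female tissue, so sex differed between Ripk3-KO and the other groups, although the labels give none. Sex is therefore confounded with genotype in both comparisons that include Ripk3-KO. The Ripk3-KO samples are also numbered apart from those of the other groups, and the labels state no batch. A batch difference, if any, could not be told apart from genotype in those comparisons. Ctrb1, a digestive protease precursor of the pancreas, was at 606 ± 8.96 CPM in WT, 16.9 ± 0.677 in Ripk3-KO and 3582 ± 263 in VilCre-Ripk3fl/fl. Scd1, a fatty acid desaturase abundant in fat tissue, was at 98.0 ± 2.6, 4382 ± 126 and 111 ± 8.68 CPM. Mitochondrial genes took 4.58 to 4.72% of counts in WT, 5.02 to 5.86% in VilCre-Ripk3fl/fl and 5.87 to 6.15% in Ripk3-KO.

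**Figure D1:**
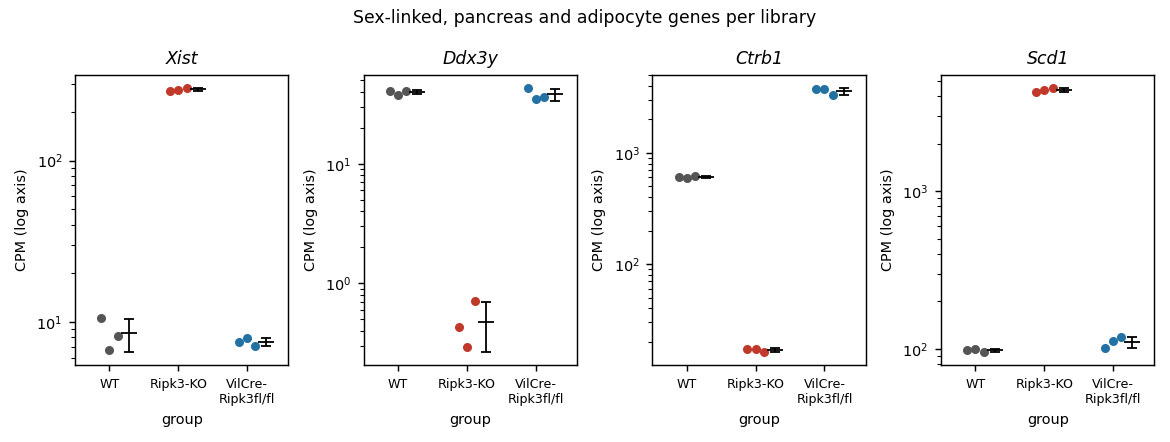
CPM (log axes) of Xist, Ddx3y, Ctrb1 and Scd1 in the 3 libraries of each group (points), with the group mean and SD (black bars). Ripk3-KO had the highest mean Xist (276 CPM) and Scd1 (4382 CPM) and the lowest Ddx3y (0.476 CPM) and Ctrb1 (16.9 CPM).

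The comparison of Ripk3-KO with WT asked which intestinal genes differ with Ripk3 deleted in the whole body. Sex-linked, pancreas and adipocyte genes also differed between these groups, so a change cannot be assigned to Ripk3 alone. Ripk3 (ENSMUSG00000022221, mm10 chromosome 14, 55784996 to 55788857) fell 31.2-fold, from 113 ± 0.979 to 3.61 ± 0.242 CPM (SD, n = 3; log2 fold change -4.96, SE 0.088, adjusted p = 1.23e-24). Genes of interferon-gamma signalling were lower. The T cell attracting chemokines Cxcl9 (ENSMUSG00000029417, chromosome 5, 92321347 to 92328079) and Cxcl10 (ENSMUSG00000034855, chromosome 5, 92346638 to 92348889) fell 4.82-fold and 6.04-fold (adjusted p = 1.95e-20 and 7.52e-20), and Ifng itself fell 7.26-fold, from 3.36 ± 0.306 to 0.459 ± 0.130 CPM (adjusted p = 1.35e-07).

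**Figure D2:**
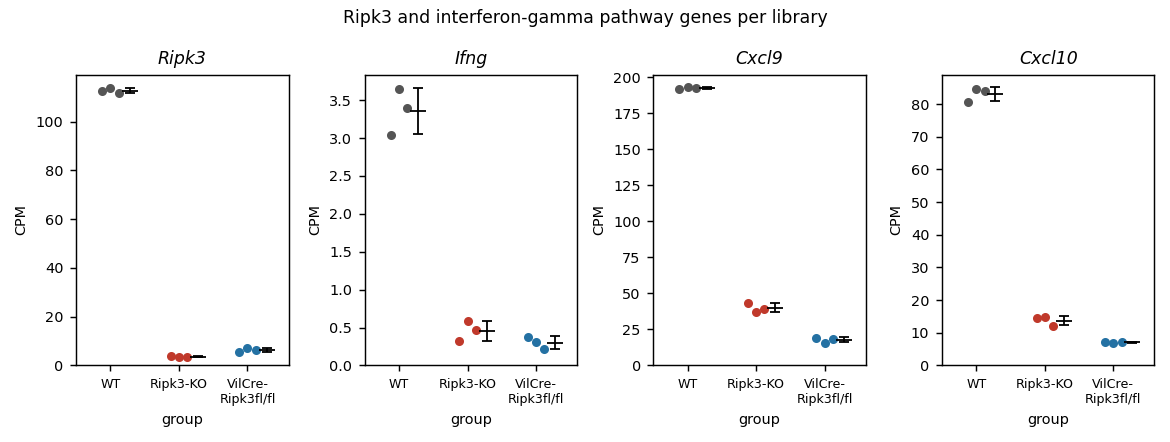
CPM of Ripk3, Ifng, Cxcl9 and Cxcl10 in the 3 libraries of each group (points), with the group mean and SD (black bars). Mean Cxcl9 was 193 CPM in WT, 40.0 in Ripk3-KO and 17.8 in VilCre-Ripk3fl/fl, and Cxcl10 was at 83.0, 13.8 and 7.05 CPM.

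Other genes fixed in advance moved less. Mlkl, which carries out necroptosis, fell 1.85-fold (adjusted p = 5.71e-11), Zbp1, a nucleic acid sensor, 1.43-fold (4.60e-09), Casp8, which restrains necroptosis, 1.32-fold (1.40e-07) and Ripk1 1.18-fold (0.00215). Ciita, the master regulator of MHC class II genes, fell 1.32-fold (4.76e-05), while the class II gene H2-Ab1 rose 1.19-fold (5.35e-05). Jak1 did not pass (112 ± 2.36 CPM in WT, 107 ± 5.06 in Ripk3-KO, adjusted p = 0.394).

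Inflammatory gene lists were mostly lower in Ripk3-KO by camera, a test of a list against all other genes. Of 30 interferon-gamma targets, 28 fell and 1 rose (median log2 fold change -0.95, adjusted p = 1.01e-23), among them Ido1, which breaks down tryptophan, 4.28-fold, and Nos2, the inducible nitric oxide synthase, 4.92-fold. Among 27 NF-kappaB targets 19 fell and 3 rose (-0.52, 1.42e-06), with the chemokine Ccl20 39.3-fold lower and Lcn2, which binds bacterial iron carriers, 7.20-fold lower. Chemokines split into 16 that fell and 7 that rose of 27 (-0.65, 0.000562), the higher ones including Ccl8 (2.57-fold) and Ccl25 (1.58-fold). Antimicrobial and acute-phase epithelial genes split into 16 lower and 6 higher of 23 (-1.08, 5.70e-10): the lectin Reg3g fell 3.03-fold and Mptx2, of Paneth cells, rose 11.3-fold. Of 19 inflammatory cytokines 12 fell and 2 rose (-0.85, 0.0223; adjusted p = 0.0769 with an estimated correlation), among them Il1b (6.54-fold lower). T and cytotoxic lymphocyte markers had 14 lower and 2 higher of 29 (-0.60, 0.0444; adjusted p = 0.113 with an estimated correlation), with the granule protease Gzma 2.01-fold lower. That call was also lost with DESeq2 (adjusted p = 0.0552), with the replicate number as a block (0.0587), without Ripk3-KO replicate 1 (0.0528) and without Ripk3-KO replicate 3 (0.0591). The range over the alternatives was 0.000583 to 0.113. Immunoglobulin segments had 83 lower and 23 higher of 153 (-1.06, 0.00638; adjusted p = 0.0657 with an estimated correlation), with Iglv3 26.7-fold lower and Igkv5-39 6.33-fold higher. With adjustment over the list alone, the counts were the same except 8 higher chemokines, 4 higher NF-kappaB targets and 25 higher immunoglobulin segments. In the same libraries 19 of 20 exocrine pancreas genes fell and 1 rose (-4.56, 3.01e-179), and 13 of 14 adipocyte genes rose (5.54, 3.23e-120).

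Several epithelial and metabolic lists were higher in Ripk3-KO. Enterocyte markers rose in 22 of 24 cases and fell in 2 (0.75, 4.47e-21), with the lactase gene Lct 4.54-fold and Ada, adenosine deaminase, 2.71-fold higher. Of 25 genes of lipid absorption and PPAR targets, 22 rose and 3 fell (0.65, 1.98e-14), led by the fatty acid transporter Cd36 (12.8-fold, from 14.9 ± 0.852 to 190 ± 0.995 CPM), which fat tissue also expresses. Xenobiotic and bile acid genes had 23 higher and 4 lower of 29 (1.09, 8.67e-21), with the drug-metabolising enzyme Cyp3a11 7.56-fold higher and the bile acid receptor Nr1h4 2.28-fold lower. Alpha-defensins, the antimicrobial peptides of Paneth cells, rose in 20 of 23 cases (2.47, 9.59e-27), with Defa29 37.7-fold higher. Paneth cell markers had 14 higher and 4 lower of 18 (1.73, 4.58e-10; adjusted p = 0.13 with an estimated correlation), with Mmp7, which activates defensins, 6.26-fold lower. Of 15 tuft cell markers 13 rose and 1 fell (1.51, 0.00383; adjusted p = 0.0657 with an estimated correlation), Sh2d6 by 9.19-fold. Cell cycle genes fell in 29 of 30 cases (-0.54, 3.11e-07), the ribonucleotide reductase gene Rrm2 by 3.12-fold. Cholesterol synthesis genes had 19 lower and 2 higher of 24 (-0.50, 1.42e-06). Goblet cell markers had 12 lower and 3 higher of 17 (-0.44, 0.000562; adjusted p = 0.102 with an estimated correlation), the mucus-processing gene Agr2 falling 2.66-fold and Clca1 rising 2.15-fold. These counts were the same when adjusted over the list alone.

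Wall and organelle lists also passed. Smooth muscle markers rose in 20 of 20 cases (1.29, 1.08e-23), Myl9, a myosin light chain, by 3.13-fold. Fibroblast and matrix genes had 17 higher and 3 lower of 24 (0.59, 9.92e-05), the proteoglycan Dcn rising 2.46-fold. Mitochondrially encoded genes rose in 12 of 13 cases (0.44, 0.00383; adjusted p = 0.347 with an estimated correlation). Nuclear oxidative phosphorylation genes rose in 18 of 29 (0.19, 0.0479; adjusted p = 0.599 with an estimated correlation). That call ended with a filter at 1 CPM (adjusted p = 0.0552) and without WT replicate 1 (0.0555), WT replicate 2 (0.0677), VilCre-Ripk3fl/fl replicate 2 (0.0518) or Ripk3-KO replicate 1 (0.114), in a range of 0.000284 to 0.599. Unfolded protein response genes had 15 lower and 3 higher of 25 (-0.25, 0.0372; adjusted p = 0.145 with an estimated correlation), a call lost with upper-quartile scaling (0.0630) and a filter at 1 CPM (0.0585), in a range of 0.00034 to 0.145. Immediate-early and stress genes had 9 higher and 5 lower of 19 (0.06, 0.0328; adjusted p = 0.118 with an estimated correlation), with Fosb 26.2-fold and Atf3 4.08-fold higher. That call was lost without a count filter (0.0746), in a range of 0.0229 to 0.118. The same counts were found when adjusted over the list alone. The Y-linked list fell in 4 of 4 cases (-6.52, 1.06e-25).

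The other lists did not pass in Ripk3-KO. Counts of members higher, lower and tested were 6, 13 and 30 for type I interferon-stimulated genes (median -0.06, adjusted p = 0.126), 4, 13 and 24 for MHC class I (-0.21, 0.101) and 2, 6 and 13 for MHC class II (-0.13, 0.248). Necroptosis and pyroptosis genes had 8, 14 and 30 (-0.13, mean 0.06, direction up, 0.972), although Gsdmc4 and Gsdmc2, of the pore-forming gasdermin family, rose 21.3-fold and 20.5-fold. Apoptosis and p53 targets had 3, 12 and 25 (-0.12, 0.126), JAK-STAT components 10, 8 and 30 (-0.03, 0.378), and tight junction genes 6, 7 and 25 (-0.05, mean 0.15, direction up, 0.972), with the claudin Cldn2 3.78-fold lower. Stem cell markers had 5, 9 and 18 (-0.14, mean 0.04, direction down, 0.489), enteroendocrine markers 9, 1 and 20 (0.42, 0.101) and B and plasma cell markers 2, 8 and 16 (-0.37, 0.237). Macrophage markers had 11, 9 and 25 (0.08, mean -0.20, direction down, 0.600), the lectin Chil3 falling 23.5-fold. Neutrophil and mast cell markers had 9, 11 and 23 (-1.07, mean -0.50, direction up, 0.330): the mast cell proteases Mcpt1 and Mcpt2 rose 9.36-fold and 9.42-fold, and the neutrophil collagenase Mmp8 fell 17.6-fold. Endothelial markers had 12, 1 and 18 (0.40, 0.101), enteric neuron and glia markers 13, 2 and 20 (0.63, 0.423), erythroid genes 5, 2 and 10 (0.71, 0.110), histone genes 9, 2 and 46 (0.29, 0.365) and T cell receptor segments 0, 3 and 6 (-1.0, 0.348). When p was adjusted over the list alone, the counts were the same except 6 higher stem cell and 13 higher endothelial markers, and 8 higher and 1 lower histone genes.

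Genes are also named by fitted change, an order that depends on the prior count where a group had 0 counts and so is no ranking of measured folds. Those higher in Ripk3-KO included Slc7a10, an amino acid transporter of fat cells (at least 81.1-fold, 0 counts in WT), the protein-coding gene RP24-346O11.2 (at least 109-fold), and Cox8b, Dmrt2 and Mup11 (at least 33.3-fold, 30.0-fold and 17.5-fold). The leptin gene Lep, Oxtr and Gys2 also rose, from 4, 1 and 2 counts in all WT libraries together, with ratios of scaled counts of 601 (95% counting interval 235 to 2208), 626 (112 to 24744) and 220 (60.7 to 1824). Without WT replicate 1 the ratio was 386 for Lep, 141 for Gys2 and at least 66.4 for Oxtr. It was at least 275 for Lep without WT replicate 3 and at least 48.6 for Gys2 without WT replicate 2. Of those lower, Pnp2, a purine nucleoside phosphorylase, went from 245 ± 3.71 to 0.994 ± 0.468 CPM. Its gene lies within 10 Mb of Ripk3 on chromosome 14, so linked DNA of another strain cannot be told apart from regulation. Rsc1a1 (within Ddi2, so its counts are uncertain) fell at least 166-fold. Lpo, Trim58, Vsig1, Gzmd and Gzme fell at least 34.9-fold, 27.0-fold, 25.7-fold, 19.6-fold and 17.8-fold, and Tuba3b fell to 5 counts (ratio 363, 95% counting interval 155 to 1121, and at least 193 without Ripk3-KO replicate 3). In all, edgeR called 9164 of 16539 genes (55.4%) at an adjusted p under 0.05, 4511 higher and 4653 lower, and 1686 and 790 of these by at least 2-fold. The median size of the called changes was 1.46-fold. Libraries of the groups did not overlap in 63.5% of genes, against 10% by chance. The camera test passed 25 of 42 lists, 15 of them also with an estimated correlation.

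In the comparison of VilCre-Ripk3fl/fl with WT, the question was what depends on Ripk3 in the epithelium. Pancreas and adipocyte genes also differed between these groups, so here too a change cannot be assigned to Ripk3 alone. Ripk3 fell 17.4-fold, to 6.45 ± 0.911 CPM (SD, n = 3; log2 fold change -4.12, SE 0.085, adjusted p = 5.24e-23). Cxcl9 fell 10.8-fold, to 17.8 ± 1.67 CPM (3.87e-23), Cxcl10 11.8-fold (1.25e-21) and Ifng 11.2-fold (3.08e-08). Mlkl fell 1.91-fold (4.86e-11), Casp8 1.18-fold (0.000208), Jak1 1.22-fold (0.000427) and Ciita 1.68-fold (6.18e-09), and H2-Ab1 rose 1.35-fold (2.51e-08). Zbp1 fell 1.12-fold (adjusted p = 0.00797), a call lost without VilCre-Ripk3fl/fl replicate 1 (0.0501, range 0.00219 to 0.0501). Ripk1 fell 1.12-fold (adjusted p = 0.0258), a call lost with upper-quartile scaling (0.0864) and without WT replicate 1 (0.0518), WT replicate 2 (0.0782) or VilCre-Ripk3fl/fl replicate 1 (0.0856), in a range of 0.0173 to 0.0864.

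Inflammatory lists were again lower. Of 30 interferon-gamma targets, 29 fell (-1.52, camera adjusted p = 1.13e-56), with Ido1 7.45-fold and the GTPase Gbp2 5.18-fold lower. Chemokines had 17 lower and 5 higher of 27 (-0.64, 3.12e-06), and NF-kappaB targets 17 lower and 6 higher of 27 (-0.67, 0.000324), with Icam1, an adhesion molecule, 5.99-fold lower and Pigr, which carries IgA across the epithelium, 2.08-fold higher. Type I interferon genes had 15 lower and 6 higher of 30 (-0.18, 0.0103), with Ifit2 8.32-fold lower. T and cytotoxic markers had 22 lower and 2 higher of 29 (-0.89, 0.00377), macrophage markers 17 lower and 3 higher of 25 (-0.34, 0.000324), among them the lysozyme Lyz2 (2.19-fold lower). MHC class I genes had 16 lower and 6 higher of 24 (-0.18, 0.00671; adjusted p = 0.242 with an estimated correlation), their regulator Nlrc5 falling 2.39-fold. Inflammatory cytokines had 12 lower and 3 higher of 19 (-0.98, 0.0190; adjusted p = 0.0652 with an estimated correlation), and Il18 rose 2.05-fold. Immunoglobulin segments had 74 lower and 28 higher of 153 (-0.84, 0.00671). Adjusted over the list alone, the counts differed only for MHC class I (7 higher), NF-kappaB (18 lower), T cell markers (24 lower), macrophages (4 higher, 18 lower) and immunoglobulins (77 lower). Here the pancreas list went the other way from Ripk3-KO, with 19 of 20 genes higher (2.91, 5.19e-149), and 13 of 14 adipocyte genes rose and 1 fell (1.51, 2.44e-10).

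Several epithelial lists rose, those of Paneth cell genes most. Alpha-defensins rose in 22 of 23 cases (4.69, 1.22e-81), with Defa29 106-fold and Defa5 25.8-fold higher, and Paneth cell markers in 16 of 18, with 2 lower (3.95, 3.85e-87). The antimicrobial list had 14 higher and 9 lower of 23 (0.92, 1.57e-08; adjusted p = 0.0572 with an estimated correlation): Ang4, a Paneth cell ribonuclease, rose 21.4-fold and the acute-phase gene Saa3 fell 22-fold. Reg1 and Reg2 of that list are also pancreas genes. Enteroendocrine markers had 15 higher and 1 lower of 20 (1.11, 1.64e-06), with the granule protein Chga 3.11-fold higher, and tuft cell markers 13 higher of 15 (1.89, 7.51e-05), with the ion channel Trpm5 3.58-fold higher. Some enteroendocrine markers, such as Chga, Sst and Gcg, are also made by pancreatic islets. Pooled counts of 3 other islet genes were 17 in WT and 2427 in VilCre-Ripk3fl/fl, so islet reads may add to this rise. The list was not tested without shared genes. Enterocyte markers had 20 higher and 1 lower of 24 (0.79, 1.01e-22), lipid absorption genes 17 higher and 7 lower of 25 (0.53, 8.86e-05) and xenobiotic genes 23 higher and 3 lower of 29 (1.16, 8.90e-24), with Cyp3a11 7.67-fold higher. Cell cycle genes had 28 lower of 30 (-0.59, 8.27e-11) and cholesterol synthesis genes 22 lower of 24 (-0.77, 1.83e-18). Smooth muscle markers had 17 higher and 1 lower of 20 (1.03, 2.11e-17). Nuclear oxidative phosphorylation genes had 27 higher of 29 (0.39, 2.51e-06; adjusted p = 0.242 with an estimated correlation) and mitochondrially encoded genes 11 higher of 13 (0.39, 0.00492; adjusted p = 0.368 with an estimated correlation). Adjusted over the list alone, the counts were the same except 23 defensins, 21 enterocyte markers and 12 higher and 1 lower mitochondrially encoded gene.

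The remaining lists did not pass in VilCre-Ripk3fl/fl. Members higher, lower and tested were 6, 4 and 13 for MHC class II (0.14, mean 0.11, direction down, 0.927), 11, 12 and 30 for necroptosis and pyroptosis (0.02, 0.373), with Gsdmc4 22.6-fold and Gsdmc2 22.7-fold higher, and 2, 11 and 25 for apoptosis and p53 targets (-0.15, 0.0642). JAK-STAT components had 5, 13 and 30 (-0.16, 0.139), tight junction genes 9, 6 and 25 (0.11, mean 0.15, direction down, 0.795), unfolded protein response genes 5, 14 and 25 (-0.14, 0.139) and stem cell markers 6, 9 and 18 (-0.21, mean 0.04, direction down, 0.669). Goblet cell markers had 4, 10 and 17 (-0.26, 0.645), with Klk1, also a pancreas gene, 4.31-fold higher and the mucin Muc2 1.59-fold lower. B and plasma cell markers had 4, 4 and 16 (-0.02, mean 0.24, direction down, 0.75), neutrophil and mast cell markers 8, 8 and 23 (-0.95, mean -0.91, direction up, 0.645), endothelial markers 11, 2 and 18 (0.34, 0.172) and fibroblast genes 6, 6 and 24 (-0.02, 0.927). Enteric neuron and glia markers had 11, 4 and 20 (0.46, 0.645), erythroid genes 3, 1 and 10 (0.14, mean -0.06, direction up, 0.797), immediate-early genes 9, 5 and 19 (0.14, 0.15), histone genes 14, 4 and 46 (0.68, 0.188), T cell receptor segments 0, 4 and 6 (-1.85, 0.148) and Y-linked genes 0, 0 and 4 (-0.13, 0.745). Adjusted over the list alone, the counts were the same except necroptosis (13 lower), apoptosis (10 lower), tight junctions (7 lower), stem cells (10 lower), neutrophil and mast cells (10 lower), erythroid genes (2 higher, 0 lower) and histones (2 lower).

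Of genes named by fitted change, which is no ranking of measured folds, Cyp3a44 rose at least 24.7-fold and Defa26 54.7-fold. The insulin genes Ins2 and Ins1, Fam151a and Il22ra2 had 6, 1, 1 and 2 counts in WT, with ratios of scaled counts of 318 (95% counting interval 146 to 869), 829 (148 to 32787), 294 (52.2 to 11652) and 67.5 (18.3 to 564). Without WT replicate 3 the ratio was at least 95.8 for Ins1 and at least 33.5 for Fam151a, and without WT replicate 1 it was 532, 189 and, for Il22ra2, at least 14.4. Defa37 rose 485-fold with a wide spread (117 ± 73.8 CPM, adjusted p = 0.000244), or 313-fold without WT replicate 1 and 317-fold without VilCre-Ripk3fl/fl replicate 1, a call lost with limma-voom (0.144) and limma-voom with quality weights (0.0931), in a range of 3.14e-05 to 0.144. Falls were found in Amy2a1 (at least 594-fold), an amylase copy, Rsc1a1 (at least 110-fold), Ly6g of neutrophils (at least 26.5-fold), BC100530 (22.2-fold or more), Gzmd (at least 12.9-fold), Gzme (at least 11.8-fold), Tff1 (at least 11.3-fold) and Tuba3b (4 counts left, ratio 301, 95% counting interval 117 to 1105, and 199 without VilCre-Ripk3fl/fl replicate 2). Names among near-identical copies, such as defensins, amylases, gasdermins and mast cell proteases, are uncertain where counting could divide reads between them. Amy2a1 fell although 19 of 20 exocrine pancreas genes rose in VilCre-Ripk3fl/fl. Whether the groups differed in strain DNA or gene copies at Amy2a1 was not tested. In all 9201 of 16539 genes were called, 4505 higher and 4696 lower, 1497 and 926 by at least 2-fold, with a median size of 1.47-fold and no overlap in 61.4% (10% by chance). The camera test passed 24 of 42 lists, 19 of them also with an estimated correlation.

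**Figure D3:**
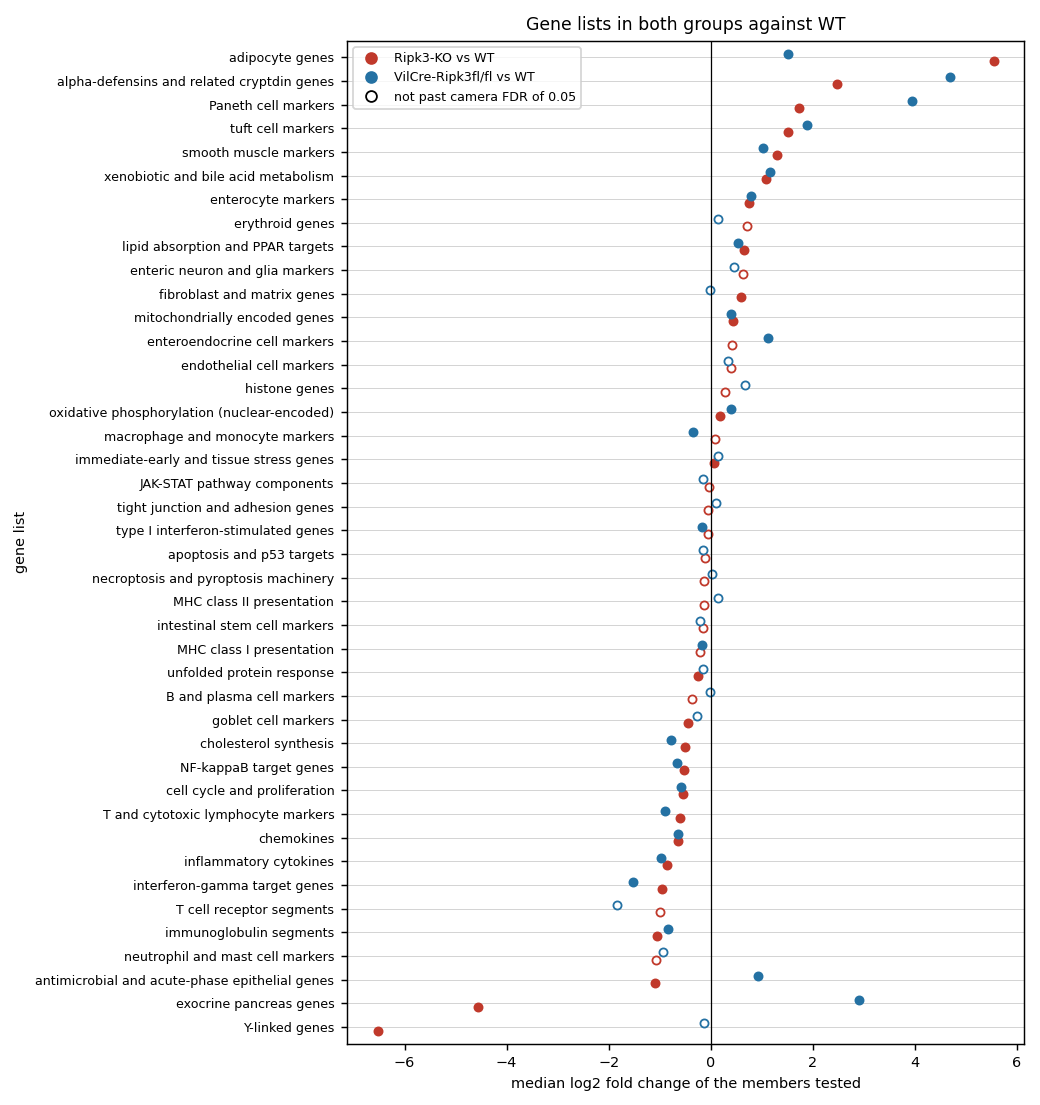
Median log2 fold change of each gene list with at least 4 tested members in Ripk3-KO (red) and VilCre-Ripk3fl/fl (blue) against WT; filled points passed camera. Interferon-gamma targets lay at -0.95 and -1.52, and the exocrine pancreas list at -4.56 and 2.91.

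Both deletions shared most changes. The same direction was called in both for 6600 genes (3091 higher, 3509 lower), against 1229 and 1321 for independent lists, and opposite directions for 355. By at least 2-fold in both, 859 were higher and 487 lower. Of the 6600, 2143 also differed between the deletions and 4457 did not pass that test. Across genes, which are not independent replicates, log2 fold changes correlated with Pearson's r of 0.634 and Spearman's rho of 0.736, and 80.7% had the same sign. The WT libraries served both comparisons and cannot be split with 3 libraries. In 20 simulations of unchanged groups against the same WT libraries, r averaged 0.497, rho 0.441, the same sign 66.7% and shared calls 0.1. The covariance was 0.716 against 0.0585 in the simulations, a difference of 0.658. The simulations took their spread from within the groups, which may be technical. Neither they nor the independent lists allow for a difference between groups in animals or dissection. The shared calls therefore cannot separate an effect of Ripk3 from a WT group that differed from both others for another reason.

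**Figure D4:**
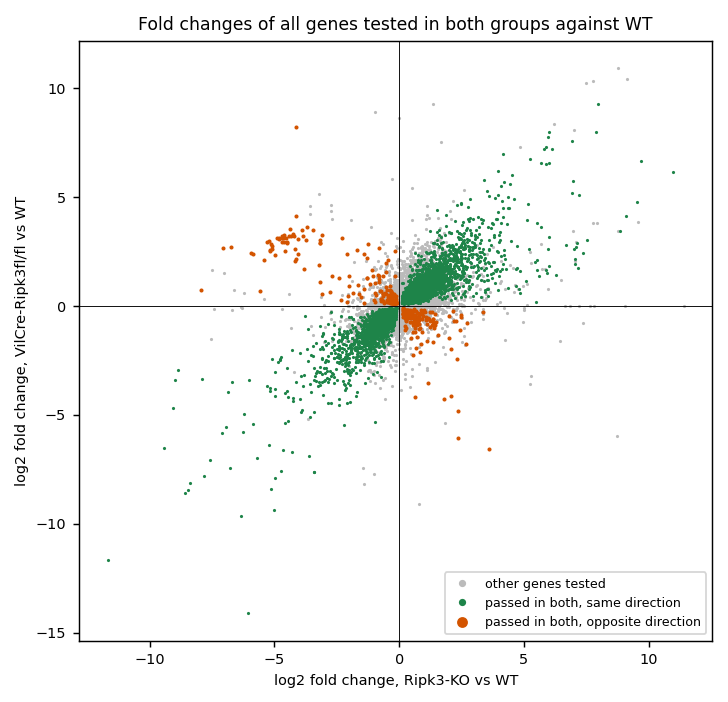
Log2 fold changes against WT of all 16539 tested genes, Ripk3-KO on the x axis and VilCre-Ripk3fl/fl on the y axis. Green points mark the 6600 genes called in the same direction in both and orange points the 355 called in opposite directions.

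The direct comparison of VilCre-Ripk3fl/fl with Ripk3-KO set the epithelial beside the whole-body deletion. Since sex-linked, pancreas and adipocyte genes also differed between these groups, a difference cannot be assigned to the site of deletion alone. Ripk3 was 1.79-fold higher in VilCre-Ripk3fl/fl (log2 fold change 0.84, SE 0.108, adjusted p = 7.85e-07). Cxcl9 was 2.25-fold lower (6.11e-13), as were Ciita (1.27-fold, 0.000754) and, among 30 interferon-gamma targets, 19, with 4 higher (-0.46, 2.61e-08). Zbp1 was 1.27-fold (7.99e-06) and H2-Ab1 1.13-fold (0.00519) higher. Casp8 was 1.12-fold higher (0.0136), a call lost without Ripk3-KO replicate 2 (0.0662, range 0.00378 to 0.0662), and Jak1 1.16-fold lower (0.00772), a call lost without VilCre-Ripk3fl/fl replicate 1 (0.0771, range 0.000356 to 0.0771). Ifng (adjusted p = 0.293), Mlkl (0.722) and Ripk1 (0.444) did not pass.

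Paneth cell and antimicrobial genes were higher in VilCre-Ripk3fl/fl than in Ripk3-KO, although Clps, Reg1 and Reg2 of these lists are also made by pancreas. Paneth cell markers were higher in 18 of 18 cases (1.82, 1.40e-62), with Ang4 7.45-fold higher, alpha-defensins in 19 of 23 (1.70, 8.86e-27) and antimicrobial genes in 17 of 23, with 2 lower (1.19, 1.57e-45), Reg3g by 4.51-fold. Goblet cell markers had 9 higher and 2 lower of 17 (0.15, 0.000436; adjusted p = 0.114 with an estimated correlation) and enteroendocrine markers 11 higher and 1 lower of 20 (0.65, 0.000936; adjusted p = 0.114 with an estimated correlation). Pancreatic islets also make some enteroendocrine markers, and the islet genes Ins1 and Ins2 were higher in VilCre-Ripk3fl/fl too. Oxidative phosphorylation genes had 22 higher of 29 (0.20, 0.00963; adjusted p = 0.695 with an estimated correlation). Fibroblast genes had 21 lower of 24 (-0.77, 6.50e-07), with Sparc 2.04-fold lower, and lipid absorption genes 15 lower and 3 higher of 25 (-0.16, 8.84e-07), with Cd36 4.65-fold lower. Cholesterol synthesis genes had 20 lower of 24 (-0.26, 0.000303; adjusted p = 0.0724 with an estimated correlation), macrophage markers 15 lower and 1 higher of 25 (-0.42, 0.000688; adjusted p = 0.0724 with an estimated correlation) and smooth muscle markers 13 lower and 1 higher of 20 (-0.32, 0.00761; adjusted p = 0.234 with an estimated correlation). All 20 pancreas genes were higher (7.55), with Ctrb1 212-fold and Cpa1 199-fold higher, all 14 adipocyte genes lower (-4.23, 1.51e-131) and all 4 Y-linked genes higher (6.41, 3.61e-38). Adjusted over the list alone, the counts differed for interferon-gamma targets (20 lower), defensins (21 higher), antimicrobial genes (18 higher), oxidative phosphorylation (23 higher), fibroblasts (22 lower), cholesterol synthesis (1 higher, 21 lower) and smooth muscle (15 lower).

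Lists that did not pass here had these members higher, lower and tested. Type I interferon genes had 5, 9 and 30 (-0.03, 0.520), MHC class II genes 6, 1 and 13 (0.18, 0.295), MHC class I genes 6, 6 and 24 (-0.06, 0.520), chemokines 5, 11 and 27 (-0.34, 0.470) and inflammatory cytokines 2, 2 and 19 (-0.02, mean -0.03, direction up, 0.826). Necroptosis genes had 8, 2 and 30 (0.02, 0.439), apoptosis genes 6, 4 and 25 (-0.01, 0.826), JAK-STAT components 4, 10 and 30 (-0.12, 0.666), NF-kappaB targets 8, 5 and 27 (0.03, 0.127) and tight junction genes 6, 4 and 25 (-0.03, mean 0.00, direction down, 0.787). Unfolded protein response genes had 12, 5 and 25 (0.13, 0.522), xenobiotic genes 9, 6 and 29 (0.04, mean -0.01, direction down, 0.826), cell cycle genes 0, 8 and 30 (-0.11, 0.520), enterocyte markers 8, 9 and 24 (-0.04, 0.666) and stem cell markers 5, 4 and 18 (-0.06, mean 0.00, direction up, 0.826). Tuft cell markers had 3, 1 and 15 (0.18, 0.520), T and cytotoxic markers 2, 7 and 29 (-0.20, 0.582), B and plasma cell markers 6, 1 and 16 (0.35, 0.439), neutrophil and mast cell markers 1, 6 and 23 (-0.17, 0.527), endothelial markers 1, 5 and 18 (-0.10, 0.781) and neuron and glia markers 1, 2 and 20 (-0.17, 0.808). Erythroid genes had 0, 5 and 10 (-0.54, 0.159), immediate-early genes 7, 8 and 19 (0.02, mean -0.11, direction down, 0.439), mitochondrially encoded genes 2, 2 and 13 (-0.09, 0.781), histone genes 2, 2 and 46 (0.21, 0.781), immunoglobulin segments 49, 36 and 153 (0.06, 0.787) and T cell receptor segments 0, 2 and 6 (-0.53, or -0.14 with a segment at 0 counts set to its bound, 0.666). Adjusted over the list alone, the counts differed for MHC class II (8 and 2), MHC class I (6 and 9), JAK-STAT (5 and 10), NF-kappaB (9 and 5), unfolded protein response (13 and 5), xenobiotic (11 and 8), cell cycle (0 and 7), B cell (6 and 2), endothelial (2 and 5), mitochondrial (2 and 4), histone (0 and 1) and immunoglobulin (49 and 38) lists.

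Of genes named by fitted change, again no ranking, Pnp2 was at 412 ± 13.1 CPM in VilCre-Ripk3fl/fl and 0.994 ± 0.468 in Ripk3-KO, Reg2 was 701-fold (1113-fold without Ripk3-KO replicate 1) and Ins2 at least 268-fold higher, and Cabp2, Mat1a, Tmed11 and BB114814 were at least 42.4-fold, 17.1-fold, 15.3-fold and 15.2-fold higher. Defa37 was 949-fold higher (adjusted p = 0.000409), with all of its Ripk3-KO counts in replicate 1, and the fold was at least 1564 without that library, 612 without Ripk3-KO replicate 3 and 621 without VilCre-Ripk3fl/fl replicate 1. It was a call lost with limma-voom (0.254) and limma-voom with quality weights (0.246), in a range of 8.76e-06 to 0.254. RP24-346O11.2 and RP23-143B2.2 were at least 90.9-fold and 15.4-fold lower, and Retn and Oxtr 44.0-fold and 42.5-fold lower. Ren1, Wfdc21, Apoc1 and Hephl1 were lower as well, at 2, 2, 6 and 5 counts in VilCre-Ripk3fl/fl, with ratios of 303 (95% counting interval 83.6 to 2506), 77.8 (21.3 to 646), 59.6 (27.2 to 163) and 54.2 (23 to 168). Without VilCre-Ripk3fl/fl replicate 3 the ratios were 194 for Ren1, 49.9 for Wfdc21 and 38.2 for Apoc1. Without VilCre-Ripk3fl/fl replicate 2 they were 51.6 for Wfdc21, 119 for Apoc1 and at least 66.7 for Ren1, and without VilCre-Ripk3fl/fl replicate 1 that of Wfdc21 was at least 18.2. In all 5244 genes were called, 2497 higher and 2747 lower, 437 and 707 by at least 2-fold, with a median size of 1.34-fold and no overlap in 40.8% (10% by chance). The camera test passed 15 of 42 lists, 9 of them also with an estimated correlation.

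The authors' deposited table also compared each deletion with WT in 26529 genes. The authors' deposited table called 3348 genes in Ripk3-KO (1808 higher, 1540 lower) and 3733 in VilCre-Ripk3fl/fl (1626 higher, 2107 lower), and 3109 and 3367 of these were also called here with the same sign, with 10 and 18 others called in the opposite direction. Its log2 fold changes, from the authors' deposited table, correlated across genes with those computed here at Spearman's rho of 0.860 and 0.866. The authors' deposited table gave Cxcl9 -1.63 (0.00206) and -2.83 (3.86e-09) and Ripk3 -4.69 and -3.88.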

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

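The tests of the 3 patterns below were chosen only after the result was seen, and the splits of the libraries were planned.

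The antimicrobial and acute-phase list differed between the 2 deletions, with a median log2 fold change of 1.19 (camera, adjusted p = 1.57e-45). Against WT the median was -1.08 in Ripk3-KO and 0.925 in VilCre-Ripk3fl/fl, where the call was lost with an estimated correlation (adjusted p = 0.0572). Reg1 and Reg2 of this list are also pancreas genes, and the list was not tested without them. The exocrine pancreas list moved in opposite directions against WT, at -4.56 and 2.91, and 7.55 between the deletions, with a camera p too small to be written other than as 0.

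The 6-library fits called 9623, 9040 and 4663 genes for Ripk3-KO against WT, VilCre-Ripk3fl/fl against WT and VilCre-Ripk3fl/fl against Ripk3-KO, and the highest count among the other splits was 0 in each. In each comparison 1 of the 10 splits, the real one, called as many, and 10 splits are too few for a share under 0.05.

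In the first pattern, libraries of a group were alike even in immunoglobulin V segment use, while sex-linked, pancreas and adipocyte genes differed between groups. Independent animals would be expected to differ in V segments, yet these varied within groups no more than other genes of like count (chi-square per degree of freedom in a ratio of at most 0.83, against 2.55 to 2.86 for 1 library of each group), so the libraries of a group may share a source of tissue or RNA. One library deposited 3 times is argued against by a chi-square per degree of freedom of at least 3.61 between libraries of a group. Attached pancreas tissue is a candidate source of the pancreas reads, since 12 of 12 acinar and islet genes outside the list were higher in VilCre-Ripk3fl/fl than in Ripk3-KO (median log2 fold change 7.40), but islet genes in WT reached only 0.586% (95% counting interval 0.341 to 0.941) of their VilCre-Ripk3fl/fl level, against 8.8 to 54% for acinar genes, which argues against tissue with the same share of islets in WT and leaves the source of its acinar reads open. Sex and pancreas reads as the cause of the shared changes are argued against by 4457 genes called the same way in both deletions and not called between them, against 1229 higher and 1321 lower for independent lists. Sex differed in Ripk3-KO only and pancreas genes moved in opposite directions, so neither would give such calls. Independent lists do not allow for the WT libraries that both comparisons share. Adipocyte reads, higher in both deletions, are not covered, and a difference between WT and both other groups in animals or dissection stays open.

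In the second pattern, genes with large changes lay near Ripk3 on chromosome 14, where DNA of another strain could have come along with the targeted allele. Among all genes, calls of at least 4-fold made up 11% of 200 genes within 10 Mb and 5.4% elsewhere in Ripk3-KO (odds ratio 2.18, 95% CI 1.32 to 3.42, Fisher's exact p = 0.00148), which fits that explanation, and 8.5% and 5.1% in VilCre-Ripk3fl/fl (1.74, 0.985 to 2.87, p = 0.0355), which left it undecided. Tandem gene clusters and list genes were left out only after these odds ratios were seen, which gave, by Fisher's exact test, 1.26 (0.592 to 2.40, p = 0.464) and 0.658 (0.210 to 1.58, p = 0.452). That smaller set leaves out called genes, such as the mast cell protease and granzyme clusters, and so excludes nothing. Pnp2, nearly absent in Ripk3-KO, was among the large calls near Ripk3 there in both sets, but not in VilCre-Ripk3fl/fl. Strain DNA therefore stays open in both groups, beside regulation of those clusters by the disease.

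In the third pattern, enterocyte genes were higher and cell cycle genes lower in both deletions than in WT. A lower share of crypts in the tissue taken could do this. Alpha-defensins, made by Paneth cells of the crypt, were higher in Ripk3-KO (median log2 fold change 2.47, SE of the mean over members 0.8, adjusted p = 0.013 with an estimated correlation) and VilCre-Ripk3fl/fl (4.69, SE 0.82, adjusted p = 0.00217). They report Paneth cells only, so a change in those cells could hide a lower crypt share. Stem cell markers, also of the crypt, did not pass by camera in Ripk3-KO (-0.14, adjusted p = 0.489) or VilCre-Ripk3fl/fl (-0.21, 0.669). A lower crypt share therefore stays open. The Paneth cell markers, which share genes with the alpha-defensin list and have the same limit, were higher in VilCre-Ripk3fl/fl (3.95, SE 1.64, adjusted p = 0.00297). They were undecided in Ripk3-KO (1.73, SE 1.53, adjusted p = 0.13). The use of alpha-defensins, of an estimated correlation and of an SE over members widened by it was settled only after these medians and p-values were known. A difference in epithelial damage or in the part of the small intestine taken was not tested.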

How the results depend on the processing

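Of the alternatives reported here, TMM factors without certain lists, leaving out X and Y genes, and leaving out pancreas-like, adipocyte and erythroid genes were chosen only after the data were seen. For the 10 main results, 200 recomputed values kept their direction and side of the threshold or stayed within 1.5 times, and 4 moved. All 4 were counts of lists passed, at 25 in Ripk3-KO against WT and 15 between the deletions with the preset correlation. The same camera test with an estimated correlation passed 15 and 9. With fry, which asks a different question of a list, 40 and 32 passed. Leaving out each library gave 8240 to 9477 genes in Ripk3-KO, 8315 to 9431 in VilCre-Ripk3fl/fl, 4069 to 5226 between the deletions and 5842 to 6559 shared genes. The log2 fold change of Ripk3 then lay between -5.02 and -4.92, -4.22 and -4.03, and 0.74 and 0.94. Upper-quartile scaling gave 5110 higher and 3952 lower calls in Ripk3-KO, 4885 and 4267 in VilCre-Ripk3fl/fl, and 2205 and 2949 between the deletions, so which direction had more calls against WT depended on scaling. With the replicate number as a block, 9211, 9247 and 5371 genes were called. The alternatives chosen later gave 9160, 9200 and 5247 genes with other TMM factors, 8882, 8932 and 5086 without 519 X and Y genes, and 9093, 9128 and 5158 without 88 pancreas-like, adipocyte and erythroid genes. For named genes 8966 values were the same, 161 lost their call, 8 gained one and 2 turned. For lists 2280 were the same, 33 lost their call, 60 gained one (43 with fry) and 21 turned.

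No result that turned direction was called, and the cause was not tested. For the list of necroptosis and pyroptosis machinery, Ripk3-KO vs WT, adjusted p-values were 0.283 without a filter, 0.765 with only 2 groups, 0.954 with DESeq2 and 0.758 to 0.998 leaving out libraries. For tight junctions in Ripk3-KO they were 0.960 without a filter and 0.897 to 0.998 leaving out libraries. For MHC class II in VilCre-Ripk3fl/fl they were 0.973 with upper-quartile scaling, 0.935 without a filter, 0.962 with DESeq2 and 0.768 (without VilCre-Ripk3fl/fl replicate 3, where it turned) to 0.953 leaving out libraries. Without a filter, necroptosis (0.889) and neutrophil and mast cell genes (0.935) turned in VilCre-Ripk3fl/fl. Fibroblast genes turned without VilCre-Ripk3fl/fl replicate 1 (0.999, range 0.830 to 0.999 leaving out libraries), and xenobiotic genes between the deletions without Ripk3-KO replicate 1 (0.994, range 0.771 to 0.994). Xist in VilCre-Ripk3fl/fl turned without WT replicate 1 (log2 fold change 0.018, range -0.335 to 0.018) and Mlkl between the deletions without Ripk3-KO replicate 1 (0.027, range -0.110 to 0.027). The alternatives for normalized values were not run, since counts were deposited, and voom was not applied to lists. Depth limits values under the floor of 0.071 to 0.127 CPM.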

Other observations

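The tests of Gene Ontology terms were chosen only after the data were seen, and the test of type 2 genes was chosen after its pattern was noticed but before the values of its genes were seen.

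Of 187 genes of ribosome biogenesis, 132 fell and 6 rose in Ripk3-KO (camera adjusted p = 3.23e-06; adjusted p = 0.137 with an estimated correlation), and 111 fell and 18 rose in VilCre-Ripk3fl/fl (0.000241; adjusted p = 0.285 with an estimated correlation). Of 298 genes of mitosis, 160 fell and 34 rose in Ripk3-KO (0.00476; 0.0313 with an estimated correlation), and 174 fell and 33 rose in VilCre-Ripk3fl/fl (0.000241; 0.00642 with an estimated correlation). In chromosome segregation 103 of 176 genes fell in each. Genes of precursor metabolites and energy went the other way, with 76 higher and 23 lower of 153 in Ripk3-KO (0.00476; 0.0964 with an estimated correlation) and 72 higher and 28 lower in VilCre-Ripk3fl/fl (0.0368; 0.260 with an estimated correlation). Of 29 terms, 3 rose and 6 fell in Ripk3-KO, and 1 rose and 5 fell in VilCre-Ripk3fl/fl, of which 4 and 2 also passed with an estimated correlation. Between the deletions camera called 0 of 29, with 2 at an unadjusted p under 0.05 and 24 by fry.

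Tuft cell markers, the mast cell protease genes Mcpt1 and Mcpt2 and the gasdermin genes Gsdmc2 and Gsdmc4 were higher in both deletions, although the tuft cell list in Ripk3-KO lost its call with an estimated correlation (adjusted p = 0.0657). A type 2 immune response, as in worm infection, may raise such genes, and the hypothesis was that at least 3 in 4 of other type 2 genes would be higher in both. Fewer than 1 in 4 was set to count against it. Of 11 such genes outside the lists 7 were tested, and 2 were higher in both. The expected share was not reached, and the count lay above the lower bound, so the hypothesis was not met but stays undecided. The 2 were Pla2g4c, a phospholipase induced by interleukin-13 (2.51 CPM in WT, 24.4 in Ripk3-KO and 39.6 in VilCre-Ripk3fl/fl), and Sprr2a1 (265, 297 and 558 CPM; 1.12-fold in Ripk3-KO). Its near-identical copies did not rise in Ripk3-KO, where Sprr2a2 had a log2 fold change of -0.09 (adjusted p = 0.135) and Sprr2a3 fell (-0.42, 3.85e-08), so the count of 2 is uncertain. Areg (82.3, 16.8 and 21.5 CPM), Gata3 (5.89, 2.57 and 4.02 CPM) and Il1rl1, the interleukin-33 receptor (20, 15.8 and 17.1 CPM), fell in both, with adjusted p-values of 0.00259 and 0.0434 for Il1rl1.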
